A study of Mus musculus with 6 samples.

How the data were processed

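Messenger RNA from the apex of mouse hearts was sequenced in 6 libraries, 3 from animals given vehicle and 3 from animals given dexmedetomidine before ischaemia and reperfusion. Per the labels, 1 µg of RNA per sample went through selection of polyadenylated RNA on poly-T beads and an NEBNext Ultra RNA kit. The authors deposited 1 table of raw counts per gene, with 1 column per library and 1 column of gene lengths in bases. Per the submitters' processing notes, Trim Galore, HTSeq and the mouse build mm9 were used. Tool versions, the aligner, the gene annotation and whether counting used strand are not given in the sources used here. Reads from a gene and an overlapping or antisense gene, and reads shared by near-identical copies, can therefore not be assigned with certainty.

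The deposited table held 37620 genes by Ensembl identifier, and 32897 of these matched a symbol in the reference gene table. The reference at hand (GENCODE M21, GRCm38) was of another build than mm9, so no coordinates are given, and it served only for symbols and for the GC content of the longest transcript of each gene. The table also held 5 summary rows that name no gene, which stayed out of library sizes and tests. Alignments at more than 1 place made up 28.0% to 39.5% of all reads in the table, reads outside any gene 2.33% to 3.63%, ambiguous reads 1.83% to 2.37%, and the remaining 2 rows were 0 in each library. Gene counts summed to between 42.7 and 56.6 M per library. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of 29.0 to 446, so each was kept as 1 sample.

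Groups came from the labels. The labels say that each group held 3 samples, but not that each came from a separate animal, so p-values measure the spread between these samples. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, robust fit, filterByExpr filter, TMM normalisation) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The filter left 14738 genes. Log2 fold changes are dexmedetomidine minus vehicle, with their standard errors (SE), and levels are CPM, counts scaled to a library of 1e6, computed from the deposited counts with TMM-scaled library sizes. The common biological coefficient of variation was 22.8%.

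Before the data were examined, 38 gene lists were fixed for cardiac metabolism, contraction, stress, inflammation, cell death, the clock, adrenergic signalling and the cell types a piece of apex could hold. Of these, 1 held sex-linked genes as a check, 1 had fewer than 5 tested members, and the other 36 were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move on balance in 1 direction, without comparing them with other genes. For each list, members were also adjusted over the list alone. Shares of counts and mean levels of cell type markers were compared by exact two-sided permutation tests, in which 3 against 3 libraries cannot give a p under 0.1.

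The rule for named genes was also fixed beforehand. It takes the 12 genes with the smallest p in each direction among those past the threshold with no overlap between the groups, or, with fewer than 5 such genes in all, the 8 with the smallest p in each direction, named as not past the threshold. It adds up to 4 members with the smallest p of each list discussed, and 16 genes named whatever their values, such as alpha-2 receptor, natriuretic peptide and cytokine genes. Models without an established symbol were passed over in the first part. Which lists to discuss was settled only after their results were seen: those past the camera threshold, those with at least 4 members past the threshold adjusted over the list alone, and the heat shock list.

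The fits were tried on simulated counts drawn from the means, dispersions and library sizes of this comparison, with 200 genes given a known change. A further small set was shifted for a trial of the list test and did not count as false when called. Genes were drawn independently, with no GC trend between libraries and no outlying library, so the rates below need not hold for the real counts. EdgeR and limma-voom ran on 14406 genes and DESeq2 on 14451. At an adjusted p of 0.05, edgeR recovered 10.6% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 95.5% of those changed 4-fold, and 10.6% of its 123 calls were false. DESeq2 recovered 24.2%, 71.6% and 97.0%, with 23.5% of 170 calls false. Limma-voom with quality weights recovered 10.6%, 55.2% and 91.0%, with 6.19% of 113 calls false.

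Alternatives fixed beforehand were the size factors of DESeq2 within edgeR, no filter, a mean CPM of at least 5, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, limma-voom with quality weights, and a prior count of 0.5 for marker levels. Alternatives for tables of normalised values did not apply to counts. After the data were seen, a correction for GC content and gene length was added, in which a loess trend (span 0.3) of each library's deviations was removed through offsets, and a fit without mitochondrially encoded genes. Of the tested genes, 97.2% had a GC value.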

Results

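Transcript levels were measured by RNA sequencing of apical heart tissue from wild-type C57/BL6J mice after 30 min of myocardial ischaemia, in which the blood supply is interrupted, and 120 min of reperfusion. Dexmedetomidine, an agonist of alpha-2 adrenergic receptors used as a sedative, had been infused by tail vein at 10 µg/kg before surgery for 3 of the 6 samples, and the other 3 came from mice given vehicle. Per the labels, the dexmedetomidine group had received the vehicle of yohimbine, an alpha-2 antagonist, 30 min before the drug, and surgery followed 20 min after it. The labels do not give this pretreatment or timing for the vehicle group, so whether the groups also differed in them is not known. Gene counts summed to 56.6, 50.3 and 51.4 M in vehicle replicates 1, 2 and 3 and to 48.6, 42.7 and 43.3 M in the dexmedetomidine replicates. The 1 comparison in this design asks which transcripts differ in the reperfused heart when dexmedetomidine was given first.

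Transcripts of the mitochondrial genome took up a larger share of the libraries after dexmedetomidine. Nuclear genes for energy metabolism, cardiomyocyte markers, ribosomal protein genes and immediate early genes were lower as groups by camera at a preset correlation. These calls and that of interferon-response genes, which were higher, were lost with an estimated correlation (camera adjusted p = 0.803 each). Mitochondrially encoded genes made up 34.0% ± 6.08 of gene counts after dexmedetomidine and 23.5% ± 1.62 after vehicle (SD, n = 3 each). Hmgn5, which codes for a nucleosome-binding protein, was 3.72-fold higher, and Dbp, a clock-controlled transcription factor, was 2.17-fold lower. The clock list did not pass camera (adjusted p = 0.383), with its activators higher and most of its output genes lower. In edgeR's quasi-likelihood test no single gene passed an adjusted p of 0.05.

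The smallest edgeR adjusted p was 0.101, and 3172 of 14738 genes had an unadjusted p under 0.05, 1841 of them higher and 1331 lower after dexmedetomidine. At the adjusted threshold DESeq2 called 1247 genes, 864 higher and 383 lower, and limma-voom with quality weights called 2063, 1296 higher and 767 lower. DESeq2 and limma-voom shared 1131 calls in the same direction. Without vehicle replicate 3 edgeR called 1251 genes (922 higher, 329 lower), 50 of the 81 named genes among them. Without dexmedetomidine replicate 1 it called 7 and without dexmedetomidine replicate 2 it called 5. On the first principal component of log2 CPM, vehicle replicates 1, 2 and 3 scored -26.3, -69.8 and 3.67, and dexmedetomidine libraries 17.6 to 46.6. Leaving out vehicle replicate 3 thus removed the vehicle library most like the dexmedetomidine libraries on that component. The 3 values of one group all lay above the 3 of the other for 27.6% of tested genes, 2300 higher and 1774 lower after dexmedetomidine. Chance gives 10% on average over splits of the libraries. Genes moved together, with 47.3% of the variance on the first principal component, so the share of a single split can lie far from that average. The share was not computed for other splits.

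None of the genes with the smallest p passed the edgeR threshold (adjusted p = 0.101 for each of the 16), though each passed in DESeq2. Hmgn5 (ENSMUSG00000031245) measured 4.25 ± 1.16 CPM after vehicle and 15.8 ± 3.797 after dexmedetomidine (SD, n = 3). Its log2 fold change was 1.90 (SE 0.25), and its DESeq2 adjusted p was 5.65e-09. Higher values were also seen for the mitochondrial ribosomal RNA mt-Rnr2 (ENSMUSG00000064339, 2.52-fold), the actin-associated Filip1l (ENSMUSG00000043336, 2.66-fold) and the cohesin acetyltransferase gene Esco1 (ENSMUSG00000024293, 2.98-fold). The splicing factor gene Rbm39 (ENSMUSG00000027620) was 2.04-fold higher, the caspase gene Casp12 (ENSMUSG00000025887) 2.32-fold, the COP9 signalosome subunit gene Cops2 (ENSMUSG00000027206) 2.24-fold and Krit1 (ENSMUSG00000000600), which acts at endothelial junctions, 1.89-fold. With a correction for GC content and length, log2 fold changes went from 1.33 to 0.47 for mt-Rnr2, from 1.22 to 0.29 for Casp12, from 1.16 to 0.27 for Cops2 and from 0.92 to 0.05 for Krit1, while Hmgn5 was at 1.42, Filip1l at 0.99, Esco1 at 0.84 and Rbm39 at 0.55.

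Among genes lower after dexmedetomidine, Inhbb (ENSMUSG00000037035), an activin and inhibin subunit, measured 27.0 ± 7.24 CPM after vehicle and 11.3 ± 1.12 after dexmedetomidine (log2 fold change -1.25, SE 0.20, n = 3). Dbp (ENSMUSG00000059824) had a log2 fold change of -1.12, the transcriptional repressors Zfp703 (ENSMUSG00000085795) and Erf (ENSMUSG00000040857) of -0.93 and -0.79, and the actin-binding protein gene Synpo (ENSMUSG00000043079) of -0.69. Fatty acid synthase, Fasn (ENSMUSG00000025153), stood at 38.0 ± 0.426 and 24.9 ± 0.729 CPM, a log2 fold change of -0.61. The endothelial transcription factor gene Sox17 (ENSMUSG00000025902) and the muscle fructose-bisphosphatase gene Fbp2 (ENSMUSG00000021456) had log2 fold changes of -0.73 and -0.74. With the correction Zfp703 was at -0.57, Erf at -0.46, Synpo at -0.44 and Fasn at -0.37.

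The size and direction of fold changes followed GC content across genes (Spearman rho -0.63, genes not being independent replicates). In 5 equal bins of genes from lowest to highest GC, median log2 fold changes were 0.47, 0.15, -0.01, -0.15 and -0.30. Genes called higher by DESeq2 had a median GC content of 40.7%, and those called lower 57.3%. When each library's GC and length trend was removed, a step chosen after seeing the data, DESeq2 called 284 genes (118 higher, 166 lower), limma-voom 182 (77 higher, 105 lower) and edgeR none, with 1799 unadjusted p under 0.05. Of the 1247 DESeq2 calls, 143 were also called with the correction in the same direction.

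**Figure D1:**
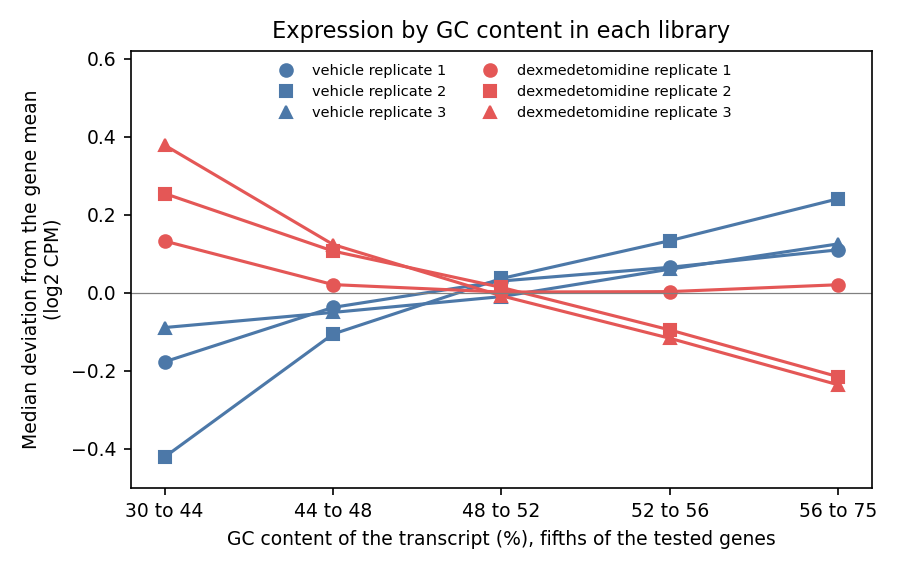
Median deviation of genes from their mean over the 6 libraries (log2 CPM, vertical axis) in 5 bins of the tested genes by GC content (horizontal axis, percent), with 1 line per library. In the lowest bin the vehicle libraries lie between -0.42 and -0.09 and the dexmedetomidine libraries between 0.13 and 0.38.

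Of 36 lists tested with camera at a preset correlation, 8 passed an adjusted p of 0.05, and the same 8 passed with the GC and length correction. With it 11 passed, the 3 added being lymphocyte markers and coagulation genes (camera adjusted p = 0.00905 each) and NF-kB feedback genes (0.0462), none of them with an estimated correlation (0.957 each). None of the 8 passed with an estimated correlation, either without the correction (adjusted p = 0.803 for each) or with it, and none by fry in 1 direction. Fry's mixed test, which lets members go both ways, passed 2 lists, fatty acid oxidation and ion channel genes (adjusted p = 0.0370 each).

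Transcripts encoded by the mitochondrial genome, which code for core subunits of the respiratory chain and of ATP synthase, were higher for 13 of 13 members (median log2 fold change 0.80, camera adjusted p = 1.74e-06 across lists, adjusted p = 0.803 with an estimated correlation). Adjusted over the list alone, 12 of 13 passed in edgeR, against 0 over all genes. The complex I genes mt-Nd2 and mt-Nd6 had log2 fold changes of 1.17 (SE 0.24) and 1.32 (SE 0.28), mt-Nd4 of 0.86 (SE 0.21) and mt-Nd4l of 0.78 (SE 0.18), and with the GC and length correction these 4 were at 0.37, 0.48, -0.00156 and 0.46. With the GC and length correction the median difference of the list in log2 CPM went from 0.78 to 0.26 and the camera adjusted p to 0.0265 (0.957 with an estimated correlation), and the levels of the groups overlapped. The mt-Nd6 gene lies on the other strand of the mitochondrial genome from most others, so without stated strand its counts can include reads of its neighbours. The share of counts in mitochondrially encoded genes was 25.2%, 22.01% and 23.3% in vehicle replicates 1, 2 and 3 and 27.1%, 36.9% and 38.2% in the dexmedetomidine replicates (exact permutation p = 0.1, the smallest possible, adjusted over 11 library measures 0.183). The mitochondrial ribosomal RNAs made up 0.523% ± 0.135 of counts after vehicle and 1.05% ± 0.0423 after dexmedetomidine (exact permutation p = 0.1, n = 3).

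**Figure D2:**
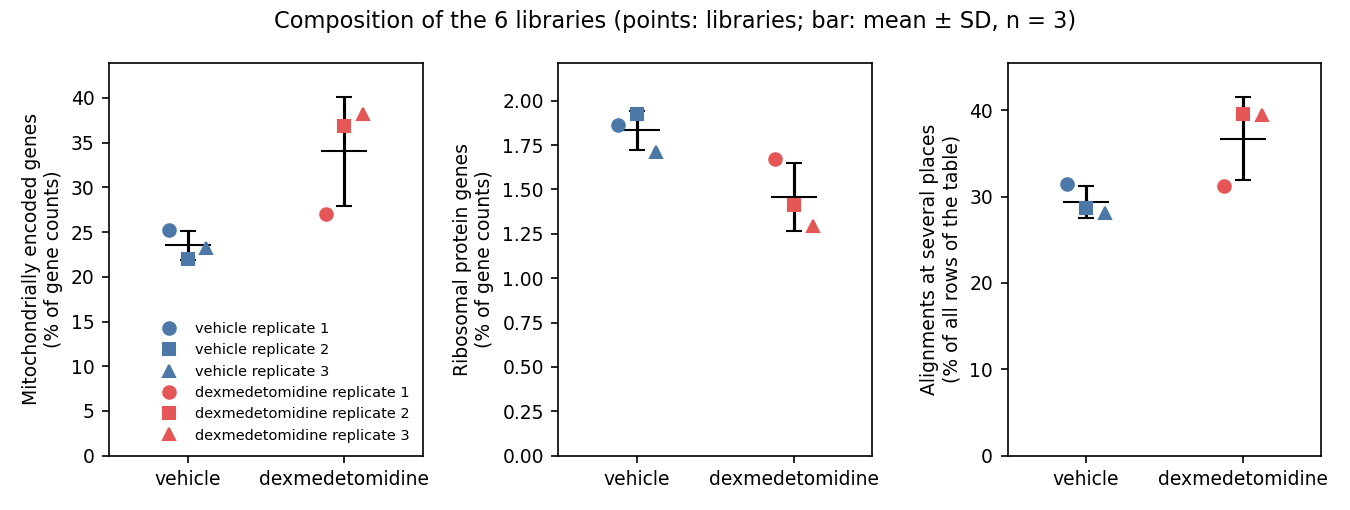
Share of mitochondrially encoded genes and of ribosomal protein genes among gene counts, and of alignments at several places among all rows (percent, vertical axes), for vehicle and dexmedetomidine libraries, with points for libraries and bars for the mean and SD of 3. All 3 dexmedetomidine libraries lie above all vehicle libraries for mitochondrially encoded genes and below them for ribosomal protein genes. Both of these shares have the same total, so a rise in one can lower the other.

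Nuclear genes for oxidative phosphorylation fell as a list, with 33 of 39 members lower (median log2 fold change -0.20, camera adjusted p = 9.64e-05, adjusted p = 0.803 with an estimated correlation), and no member passed adjusted over the list alone or over all genes. The members with the smallest p were Ndufa2 of complex I (-0.87, SE 0.24), the cytochrome c oxidase subunits Cox6a2 (-0.79, SE 0.22) and Cox5b (-0.82, SE 0.25), and Atp5d of ATP synthase (-0.49, SE 0.15, and -0.16 with the GC and length correction). Genes of glycolysis and glucose use fell for 22 of 25 members (median -0.29, camera adjusted p = 0.000164, adjusted p = 0.803 with an estimated correlation, 0 past adjusted over the list alone or over all genes). Their median difference in log2 CPM went from -0.29 to -0.15 with the GC and length correction (camera adjusted p = 0.0284, 0.957 with an estimated correlation). Slc16a3, a lactate exporter, had a log2 fold change of -1.36 (SE 0.32), the muscle phosphoglycerate mutase Pgam2 of -0.54 and hexokinase 1, Hk1, of -0.39, while the kinase gene Pfkfb2 was at 0.55. With the correction Pgam2, Hk1 and Pfkfb2 were at -0.20, -0.20 and 0.19, and Pfkfb2 was at 0.35 without dexmedetomidine replicate 3.

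Genes of fatty acid oxidation fell for 26 of 30 members (median -0.23, camera adjusted p = 0.000717, adjusted p = 0.803 with an estimated correlation). Adjusted over the list alone 8 passed in edgeR, against 0 over all genes. They included Mlycd, malonyl-CoA decarboxylase, with a log2 fold change of -0.69 (SE 0.14, and -0.38 with the correction), the lipase inhibitor gene Angptl4 at -0.61 (SE 0.14), the fatty acid binding protein gene Fabp3 at -0.75 (SE 0.19) and the acyl-CoA thioesterase gene Acot1 at -0.98 (SE 0.21). Acot1 has near-identical neighbours in its family, so its counts are uncertain. Without dexmedetomidine replicate 1 the list had a camera adjusted p of 0.102. Pdk4, a fasting-induced kinase that limits glucose oxidation, measured 2054 ± 118 CPM after vehicle and 2578 ± 974 after dexmedetomidine, with no call (log2 fold change 0.33, SE 0.27, edgeR adjusted p = 0.517). It was at 0.07 with the correction and between 0.15 and 0.61 with 1 library left out.

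Cardiomyocyte markers fell for 16 of 19 members (median -0.32, camera adjusted p = 0.000747, adjusted p = 0.803 with an estimated correlation), and 11 passed adjusted over the list alone in edgeR, against 0 over all genes. Myh6, the main myosin heavy chain of the adult mouse ventricle, measured 17446 ± 1628 CPM after vehicle and 12577 ± 1778 after dexmedetomidine (log2 fold change -0.47, SE 0.14). The sarcomeric Tcap was at -0.62 (SE 0.16) and desmin, Des, at -0.54 (SE 0.16). With the GC and length correction Myh6 was at -0.27, Tcap at -0.14 and Des at -0.32. Pln, which codes for the calcium pump inhibitor phospholamban, was at 0.48 (SE 0.14) and at -0.25 with the correction. Mean cardiomyocyte marker level was 11.8 ± 0.136 log2 CPM after vehicle and 11.5 ± 0.0781 after dexmedetomidine, and the endothelial level 6.43 ± 0.0371 and 6.27 ± 0.0638 (exact permutation p = 0.1 for both, adjusted over 12 marker lists 0.6).

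Ribosomal protein genes fell for 68 of 84 members (median -0.22, camera adjusted p = 5.41e-06, adjusted p = 0.803 with an estimated correlation, 0 past adjusted over the list alone or over all genes). Rpl38, Rps9, Rpl13 and Rplp1 had log2 fold changes of -0.60, -0.56, -0.58 and -0.60, and of -0.18, -0.48, -0.51 and -0.23 with the GC and length correction. Since many of these genes have processed pseudogenes, single values are uncertain. The groups overlapped at the level of the list, with mean deviations of 0.16, 0.26 and -0.085 in the vehicle libraries and -0.036, -0.091 and -0.21 in the dexmedetomidine libraries. Ribosomal protein genes made up 1.83% ± 0.111 of counts after vehicle and 1.46% ± 0.193 after dexmedetomidine (exact permutation p = 0.1, n = 3). The total includes mitochondrially encoded genes, at 23.5% after vehicle and 34.0% after dexmedetomidine. A larger mitochondrial part in itself lowers the ribosomal protein share, so these shares are not independent of each other.

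Immediate early genes, which respond within minutes to stress and growth signals, fell for 27 of 28 members (median -0.89, camera adjusted p = 4.56e-05, adjusted p = 0.803 with an estimated correlation, 0 past adjusted over the list alone or over all genes). At the level of the list the groups overlapped, with mean deviations of 0.18, 1.32 and -0.39 in the vehicle libraries and -0.085, -0.45 and -0.58 in the dexmedetomidine libraries. Values of the groups did not overlap for 3 of 28 members, against 27.6% of all tested genes. The phosphatase gene Dusp1 stood at 202 ± 70.6 CPM after vehicle and 125 ± 7.95 after dexmedetomidine (log2 fold change -0.70, SE 0.22). The transcription factor genes Egr3, Junb and Jund had log2 fold changes of -1.58, -1.21 and -1.17. Junb and Jund were at -0.76 and -0.59 with the GC and length correction. Vehicle replicate 2 stood apart from the other libraries, with Fos at 608 CPM against 34.3 and 39.9 CPM in vehicle replicates 1 and 3 and between 21.8 and 60.1 in the dexmedetomidine libraries. Without that replicate the list median was -0.27, with 22 of 28 members lower and a camera adjusted p of 0.0141 (0.731 with an estimated correlation), and Fos was at a log2 fold change of 0.16 where it had been -2.46 (SE 1.35) with all libraries. Dusp1, Egr3, Junb and Jund were then at -0.37, -0.91, -0.62 and -0.68.

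The inducible heat shock gene Hspa1a measured 77.6, 767 and 43.7 CPM in vehicle replicates 1, 2 and 3 and 110, 118 and 25.9 in the dexmedetomidine replicates. Its counts are uncertain because Hspa1b is nearly identical. The heat shock list did not pass (camera adjusted p = 0.79, median log2 fold change -0.10, 11 of 19 lower while the test pointed up), but without vehicle replicate 2 it was higher for 15 of 19 members, with a median of 0.48 and a camera adjusted p of 0.00773 (0.731 with an estimated correlation). Hspa4l and Chordc1, chaperone and co-chaperone genes, had log2 fold changes of 0.66 (SE 0.12) and 0.83 (SE 0.15) and passed adjusted over the list alone, 2 of 19 against 0 over all genes, and Hsp90aa1 and Bag3 were at 0.81 and -0.63. With the GC and length correction Hspa4l was at -0.29, Chordc1 at -0.15, Hsp90aa1 at 0.43 and Bag3 at -0.41, and without vehicle replicate 2 Bag3 was at -0.12.

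**Figure D3:**
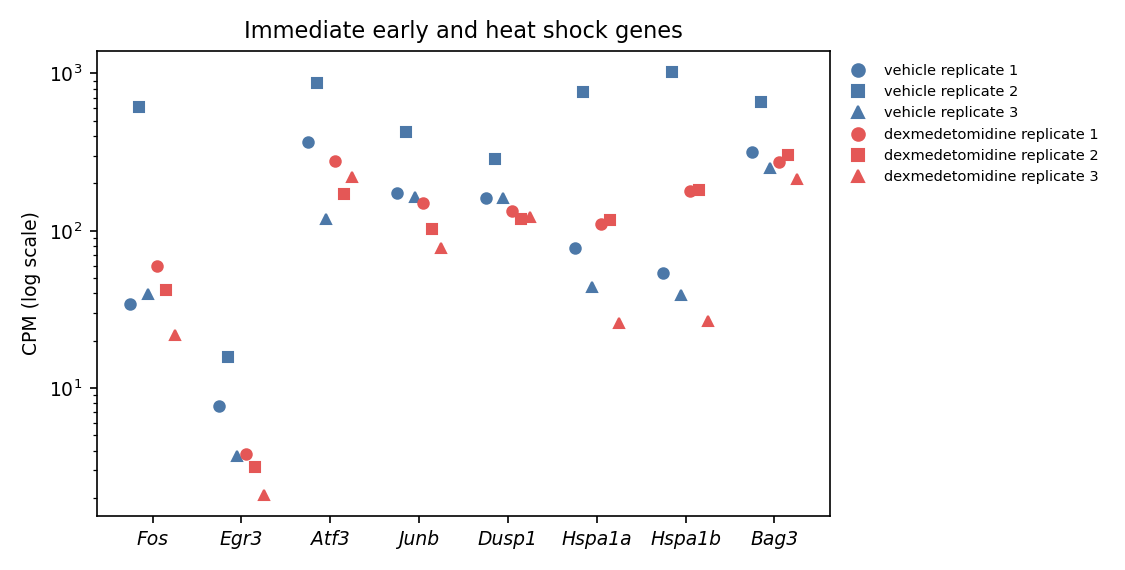
Levels of immediate early genes (Fos, Egr3, Atf3, Junb, Dusp1) and stress protein genes (Hspa1a, Hspa1b, Bag3) in each library (CPM, log scale), with 1 point per library. Vehicle replicate 2 is the highest library for each gene, at 608 CPM for Fos and 767 for Hspa1a.

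Interferon-response genes, which are antiviral effectors and sensors, rose as a list, with 19 of 22 members higher (median 0.36, camera adjusted p = 0.0150, adjusted p = 0.803 with an estimated correlation). Adjusted over the list alone, 4 passed in edgeR against 0 over all genes. These were Ifit1 (log2 fold change 1.29, SE 0.32), Ifi44 (1.21, SE 0.26), the RNA sensor gene Ifih1 (0.85, SE 0.21) and Oasl2 (0.62, SE 0.16). The corrected values for GC and length were 0.95, 0.49, 0.32 and 0.59. Ifit1 measured 15.4, 31.2 and 25.6 CPM in vehicle replicates 1, 2 and 3 and 76.1, 63.4 and 37.1 in the dexmedetomidine replicates. The groups overlapped at the level of the list, where mean deviations were -0.49, 0.08 and -0.18 in the vehicle libraries and 0.73, 0.20 and -0.34 in the dexmedetomidine libraries. The list did not pass without vehicle replicate 1 (adjusted p = 0.140), vehicle replicate 3 (0.0619) or dexmedetomidine replicate 1 (0.406).

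**Figure D4:**
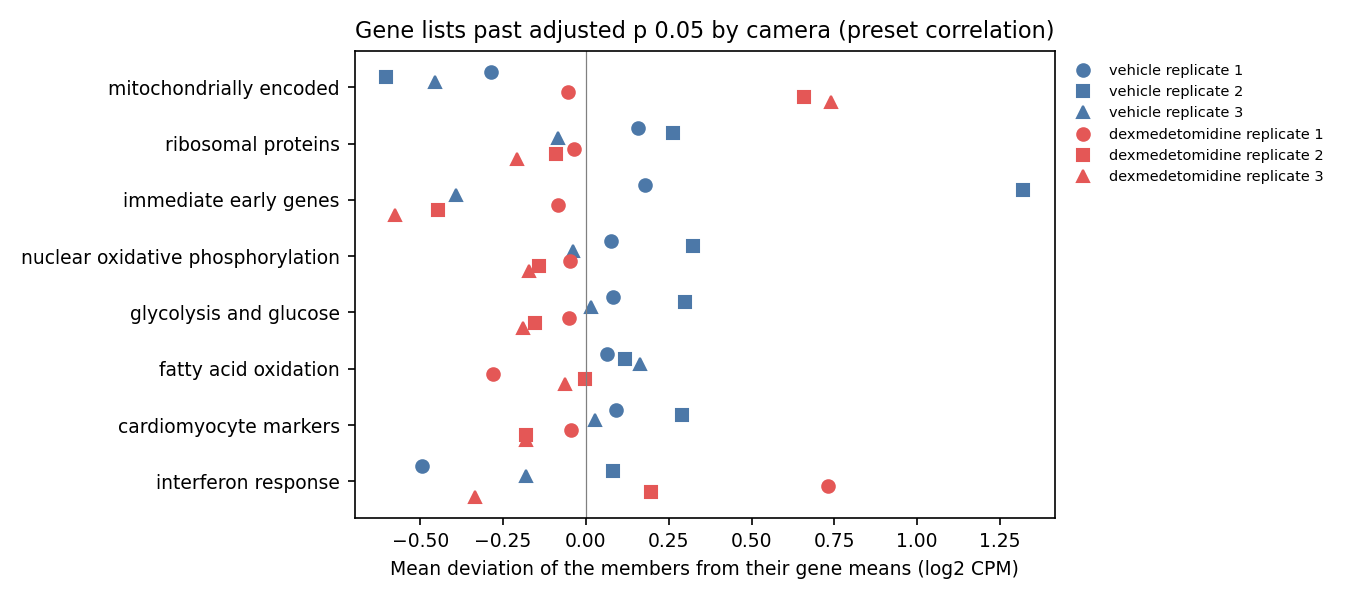
Mean deviation of list members from their gene means in each library (log2 CPM, horizontal axis) for the 8 lists past the camera threshold, with 1 point per library. Mitochondrially encoded genes lie at -0.29, -0.60 and -0.45 in the vehicle libraries and at -0.05, 0.66 and 0.74 in the dexmedetomidine libraries, and immediate early genes reach 1.32 in vehicle replicate 2.

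The circadian clock list did not pass camera (adjusted p = 0.383), with 7 of 20 members higher and 13 lower, but 8 of its members passed adjusted over the list alone in edgeR, against 0 over all genes. The activators Clock, Arntl and Npas2 were at log2 fold changes of 1.08 (SE 0.19), 1.16 (SE 0.39) and 0.95 (SE 0.33), and the nuclear receptor gene Rora at 1.21 (SE 0.29). Lower values were found for the clock output gene Dbp (-1.12, SE 0.20) and for the repressors Cry2 (-0.63, SE 0.15), Cry1 (-0.62, SE 0.18) and Per1 (-0.46, SE 0.12). Of 10 clock output genes, Nr1d2 (0.44, SE 0.17), Hlf (0.05, SE 0.28) and Nr1d1 (0.04, SE 0.20) were not lower. Arntl, Npas2, Cry1, Nr1d2, Hlf, Nr1d1 and, further below, Bhlhe41 were named after their values were seen. Clock had a GC content of 40.9% and Dbp of 61.6%, and with the GC and length correction they were at 0.38 (SE 0.11) and -0.73 (SE 0.19). Rora was then at 0.52, Cry2 at -0.44 and Per1 at -0.13, and Arntl and Npas2 at 1.09 and 1.01.

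**Figure D5:**
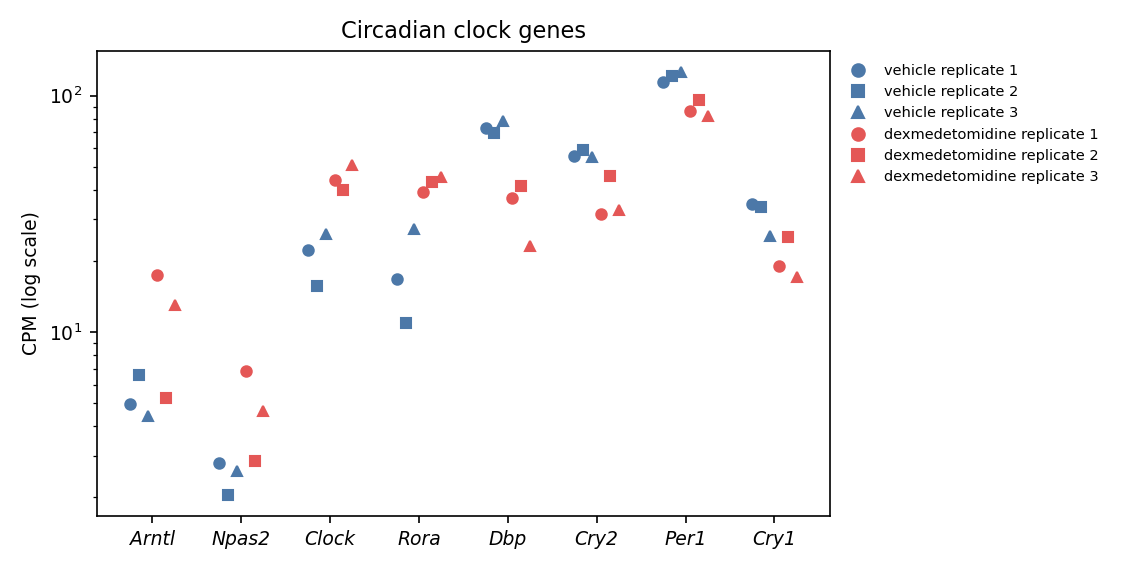
Levels of 8 circadian clock genes in each library (CPM, log scale), with 1 point per library. Dbp lies between 69.3 and 77.8 CPM in the vehicle libraries and between 23.2 and 41.4 in the dexmedetomidine libraries.

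Calcium handling and ion channel genes did not pass as a list (camera adjusted p = 0.765, 13 higher and 10 lower). Of 23 members 5 passed adjusted over the list alone, against 0 over all genes. Trdn, which codes for triadin of the calcium release complex, measured 68.3 ± 20.9 CPM after vehicle and 202 ± 66.9 after dexmedetomidine (log2 fold change 1.57, SE 0.30, n = 3), and 0.57 with the GC and length correction. The potassium channel genes Kcnj3 and Kcnd2 were at 0.65 and 0.43 (0.29 and 0.09 with the correction), and Camk2d, a calcium-dependent kinase gene, was at 0.38 and at -0.17 with the correction. Matrix remodelling genes did not pass either and went both ways (camera adjusted p = 0.886, 10 higher and 12 lower, median log2 fold change -0.09). Adjusted over the list alone 4 of 22 members passed, against 0 over all genes. These 4 were the collagen cross-linking enzyme gene Lox (0.86, SE 0.15), the TGF-beta receptor gene Tgfbr1 (0.82, SE 0.16), Tgfb2 (0.65, SE 0.17) and the stromelysin gene Mmp3 (0.64, SE 0.17). Genes of pyroptosis, necroptosis and ferroptosis went both ways (camera adjusted p = 0.513, 12 higher and 11 lower), and 5 of 23 passed adjusted over the list alone against 0 over all genes. Tfrc, the transferrin receptor gene, was at 1.05 (SE 0.24), Casp4 at 0.63 (SE 0.17), Acsl4 at 0.53 (SE 0.16) and the ferritin light chain gene Ftl1 at -0.64 (SE 0.15). With the GC and length correction Casp4 and Acsl4 were at -0.25 and -0.29, Tfrc at 0.22, Ftl1 at -0.31 and Tgfbr1 at 0.12, while Lox, Tgfb2 and Mmp3 were at 0.50, 0.50 and 0.49.

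Alpha-2 receptor transcripts were scarce in this tissue. Adra2a had 0 to 4 counts per library and was not tested, Adra2b measured 1.58 ± 0.945 CPM after vehicle and 1.14 ± 0.520 after dexmedetomidine, and Adra2c 0.178 ± 0.125 and 0.187 ± 0.141. Nisch, the imidazoline receptor candidate gene, stood at 174 ± 9.71 and 166 ± 6.31 CPM. The natriuretic peptide genes Nppa and Nppb had log2 fold changes of -0.83 (SE 0.37) and -0.75 (SE 0.48), with edgeR adjusted p of 0.245 and 0.409. Myh7, the fetal myosin gene, was at -0.67 (SE 0.18) and Hmox1, the haem-degrading enzyme gene, at -1.08 (SE 0.39), with edgeR adjusted p of 0.109 and 0.171. Without vehicle replicate 2 Nppa was at -0.51, Nppb at -0.09, Hmox1 at -0.61 and Atf3 at -0.13, and without vehicle replicate 3 Nppb was at -1.15 and Atf3 at -1.48, both past the edgeR threshold there. The cytokine genes Il6 (0.01, SE 0.30) and Il1b (0.92, SE 0.49) and the stress-induced Atf3 (-1.02, SE 0.60) had edgeR adjusted p of 0.985, 0.315 and 0.369. Il1b was at 0.58 without dexmedetomidine replicate 2 and at 1.56, past the threshold, without vehicle replicate 3.

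The remaining lists did not pass camera with all libraries and no correction. Fetal and stress genes of the heart had an adjusted p of 0.0505, antioxidant genes and cyclic AMP targets 0.0549 each, NF-kB feedback and adhesion genes 0.101, lymphocyte markers 0.109, coagulation genes 0.129, endothelial markers 0.148 (0.0466 without vehicle replicate 2, and 0.803 with all libraries and an estimated correlation) and adrenergic receptor and G protein genes 0.248. Mural cell markers were at 0.319, cell cycle genes and neutrophil markers at 0.321, adipocyte markers at 0.466, atrial and conduction markers at 0.593, and cytokines and glucocorticoid targets at 0.790. Apoptosis genes and erythroid markers were at 0.831, fibroblast markers at 0.860, unfolded protein response, autophagy and Schwann cell genes at 0.886, hypoxia genes at 0.923 and macrophage markers at 0.982. The mesothelial list had 4 tested members, a median log2 fold change of 0.34 and no test. The mean lay above 0 and the median below it for adipocyte (0.31, -0.28), atrial (0.33, -0.07), Schwann cell (0.12, -0.01) and glucocorticoid genes, and the reverse held for unfolded protein response (-0.02, 0.08) and autophagy genes. The hypoxia list pointed down in the test with a median of 0.04, and the Schwann cell list pointed up. Mean neutrophil marker level was 2.13 ± 0.458 log2 CPM after vehicle and 2.49 ± 0.933 after dexmedetomidine (exact permutation p = 0.6, n = 3). Xist had 0 to 11 counts and Y-linked genes were present in each of the 6 libraries. The 4 Y-linked genes had a median log2 fold change of 1.05, with 4 of 4 past the threshold adjusted over the list alone in edgeR, 0 over all genes and no overlap between the groups. Their log2 CPM differences were 1.65 for Ddx3y, 1.44 for Uty, 0.83 for Eif2s3y and 0.41 for Kdm5d, and 0.57, 0.23, -0.19 and 0.01 with the GC and length correction.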

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

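The comparison of this share between groups was chosen after the counts were seen. Alignments at more than 1 place, which the gene tests did not use, made up 36.7% ± 4.79 of all reads in the table after dexmedetomidine and 29.4% ± 1.82 after vehicle (SD, n = 3). This entry was singled out because reads outside the main measurement stood above the level of the control group. Values were 31.4%, 28.6% and 28.0% in vehicle replicates 1, 2 and 3 and 31.2%, 39.5% and 39.4% in the dexmedetomidine replicates (exact permutation p = 0.2), so dexmedetomidine replicate 1 lay among the vehicle libraries. Which genes these reads came from is not recorded in the table, and no explanation was tested.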

How the results depend on the processing

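The GC and length correction and the fit of nuclear genes alone were chosen after the result was seen, and the other alternatives before. The count of genes past the edgeR threshold was 0 (3172 with an unadjusted p under 0.05), and it was also 0 with DESeq2 size factors in edgeR, a mean CPM of at least 5, nuclear genes alone and the correction in edgeR. It was 406 (292 higher, 114 lower) without a filter, 1247 (864, 383) by DESeq2 and 2063 (1296, 767) by limma-voom with quality weights, and with the correction 284 (118, 166) and 182 (77, 105). Leaving out 1 library gave 0 to 1251 genes, 0 to 922 higher and 0 to 329 lower. The highest counts came without vehicle replicate 3, the vehicle library nearest to the dexmedetomidine libraries on the first principal component. The cause was not tested. The labels do not say whether equal replicate numbers mark paired samples. With group means removed, log2 CPM of libraries with equal numbers correlated at -0.055, 0.036 and 0.15 for replicates 1, 2 and 3. These low values do not show pairing. With the replicate number as a block the count of genes was 636 (569 higher, 67 lower). With that block fetal and stress, antioxidant and cyclic AMP target genes also passed camera at the preset correlation, and without a block they had an adjusted p of 0.803 each with an estimated correlation.

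With the correction, log2 fold changes crossed 0 for Nisch (0.14), Il6 (-0.52), mt-Nd4 (-0.00156), Pln (-0.25), Casp4 (-0.25), Acsl4 (-0.29), Camk2d (-0.17), Hspa4l (-0.29) and Chordc1 (-0.15), and 72 of 81 named genes kept their direction. Leaving out 1 library, ranges that crossed 0 were -0.86 to 0.0101 for Adra2b, -0.41 to 0.58 for Adra2c, -2.97 to 0.16 for Fos, -0.27 to 0.21 for Il6 and -2.32 to 0.48 for Hspa1a.

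With an estimated correlation 0 of 36 lists passed camera, against 8, and each of the 8 had an adjusted p of 0.803. By fry 0 passed in 1 direction (2 by its mixed test), with adjusted p of 0.524 for immediate early, 0.607 for interferon, 0.310 for cardiomyocyte and for glycolysis, 0.302 for fatty acid oxidation and for mitochondrially encoded, 0.483 for oxidative phosphorylation and 0.491 for ribosomal protein genes. The direction by fry turned for autophagy (0.963), hypoxia (0.927) and matrix genes (0.788). With the correction, camera's direction turned for adipocyte, atrial, unfolded protein response, cell death and adrenergic genes (adjusted p 0.984 each), ion channel and glucocorticoid genes (0.431 each) and heat shock genes (0.962). It turned for macrophage and hypoxia genes without a filter (0.996 each), and for macrophage (0.901) and autophagy genes (0.943) at a mean CPM of at least 5.

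Leaving out 1 library, camera adjusted p ranged from 7.25e-07 to 0.406 for interferon and 6.26e-05 to 0.102 for fatty acid oxidation genes. It ranged from 0.0874 to 0.952 for cytokines, 0.000179 to 0.720 for neutrophil, 0.293 to 0.820 for macrophage, 0.419 to 0.977 for fibroblast, 0.467 to 0.746 for erythroid and 0.714 to 0.977 for Schwann cell markers. Ranges were 0.470 to 0.977 for glucocorticoid, 0.00773 to 0.898 for heat shock, 0.419 to 0.977 for unfolded protein response, 0.599 to 0.987 for apoptosis, 0.652 to 0.927 for autophagy, 0.591 to 0.977 for hypoxia and 0.335 to 0.977 for matrix genes. Some lists that did not pass with all libraries passed at the preset correlation when 1 was left out. With all libraries and an estimated correlation their adjusted p was 0.803 each, and 0.959 for neutrophil and heat shock genes. Ranges were 0.000699 to 0.330 for fetal and stress, 0.00723 to 0.406 for antioxidant, 0.00886 to 0.419 for cyclic AMP target, 0.0127 to 0.467 for NF-kB, 0.0140 to 0.406 for coagulation, 0.0343 to 0.481 for lymphocyte and 0.0466 to 0.299 for endothelial genes. Without a filter antioxidant and cyclic AMP target genes also passed at the preset correlation. Differences in percent ranged from -0.0126 to 0.00255 for haemoglobin and -0.0656 to 0.587 for reads outside genes. Marker levels ranged from -0.00259 to 0.13 for fibroblast, -0.0531 to 0.87 for neutrophil, -0.10 to 0.18 for macrophage, -0.0261 to 0.22 for erythroid, -0.13 to 0.67 for adipocyte, -0.0129 to 0.76 for mesothelial and -0.27 to 0.37 for atrial markers.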

Other observations

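The tests of GC content, mitochondrially encoded, immediate early, heat shock and clock genes, and of genes grouped by symbol, were chosen after the result was seen, while the test of depth, the counts of other splits, and leaving out a library or estimating the correlation as single alternatives were set before.

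Fold changes followed GC content, with mitochondrially encoded genes, low in GC, higher after dexmedetomidine. A lower number of reads in itself is argued against, since rho was -0.63 before and -0.64 after thinning to the smallest library. A larger share of cardiomyocyte RNA would raise cardiomyocyte markers. These had a median log2 fold change of -0.32, and each dexmedetomidine library lay below each vehicle library. With the GC and length correction their median log2 CPM difference was -0.27. The list had a camera adjusted p of 0.803 with an estimated correlation. Its members also moved with GC content, as Pln (38.6% GC) was at 0.48 and at -0.25 with the correction. The markers thus showed no rise, but a larger share is not excluded. GC slopes were 2.45 (SD 1.56) after vehicle and -2.45 (SD 1.43) after dexmedetomidine without overlap (exact permutation p = 0.1, n = 3), a difference of 4.89 against ranges of 2.95 and 2.82 within the groups, the larger of which was 1.36 times the gap between the nearest libraries. For the mitochondrially encoded genes the correction left a median of 0.26 from 0.78, a camera adjusted p of 0.0265 (0.957 with an estimated correlation) and groups that overlapped. A technical GC trend between libraries cannot be told apart from an effect of dexmedetomidine on these genes or on transcripts low in GC, since the trend runs along with the groups and the correction removes any such trend whatever its source.

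Immediate early genes were lower after dexmedetomidine, and vehicle replicate 2 was the highest library for 28 of 28 of them and for 13 of 19 heat shock genes, though not for Hsp90aa1, Chordc1 or Hspa4l. That replicate had a first principal component score of -69.8, at the far vehicle end, where dexmedetomidine libraries scored 17.6 to 46.6. The scores ran in the order of the GC slopes, from 4.21 in vehicle replicate 2 to -3.72 in dexmedetomidine replicate 3. They therefore cannot decide whether that replicate was swapped with a dexmedetomidine library. Without vehicle replicate 2 the median log2 fold change of immediate early genes went from -0.89 to -0.27, with a camera adjusted p of 0.0141 (0.731 with an estimated correlation). With the GC and length correction the median log2 CPM difference went from -0.69 to -0.49, with 0.000917 (0.957 with an estimated correlation). The levels of the groups overlapped in both settings, and also with all libraries and no correction. Thus that replicate alone and the GC trend cannot be told apart from an effect of dexmedetomidine, which stays open and untested.

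Clock activators were higher and 7 of 10 clock outputs lower after dexmedetomidine, while the outputs Nr1d2, Hlf and Nr1d1 were above 0. The GC trend alone is argued against, since the difference between these arms was 1.32 before and 1.05 after the correction, and the groups stayed apart (exact permutation p = 0.1, n = 3), though dexmedetomidine replicate 2 lay close to the vehicle libraries. A different clock time at harvest cannot be told apart from an effect of dexmedetomidine, since no harvest time is given in the sources used here. The mark for such a shift, set after the result was seen, was at least 9 of 10 outputs lower with 3 of 3 activators higher. The values were 7 of 10 and 3 of 3 without the correction and 9 of 10 and 3 of 3 with it. With the correction only Dbp (-0.73, SE 0.19) and Bhlhe41 (-0.83, SE 0.31) of the outputs had an unadjusted edgeR p under 0.05, so the count of signs cannot decide.

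The 6 libraries can be split into equal groups in 10 ways, so a share of splits under 0.05 cannot be reached. EdgeR called 0 genes in the real split and at most 0 in the others, so 10 of 10 gave as many, with 3172 and at most 1775 at an unadjusted p under 0.05 (1 of 10 as many). DESeq2 called 1247 genes and at most 80 in the others (1 of 10 as many). Camera called 8 lists in the real split, and 8 of 10 splits gave as many, with up to 17 when vehicle replicates 1 and 3 and dexmedetomidine replicate 3 were set against the rest. The number of lists past the threshold at a preset correlation therefore carries little weight.

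Of 92 symbol stems with enough genes, 5 passed camera at a preset correlation (Zfp, Rpl, Rps, Ifi and Cox) and 0 with an estimated correlation. Genes whose symbols begin with Zfp, mostly zinc finger genes, were higher for 248 of 333, with a median log2 fold change of 0.42 and a camera adjusted p of 6.72e-08 (0.912 with an estimated correlation). Rpl, Rps and Cox genes had medians of -0.27, -0.21 and -0.19 and Ifi genes of 0.56, with camera adjusted p of 1.48e-06, 0.00750, 0.0467 and 0.0193. With the GC and length correction the median difference was 0.22 for Zfp and -0.17 for Rpl genes, with camera adjusted p of 1.41e-07 and 0.00156. Rps (0.166), Ifi (0.229, with a median of 0.16) and Cox genes (0.345) no longer passed, Mrps (0.0113) and Col genes (0.00111) did, and each of these stems was at 0.901 with an estimated correlation. Against the uncorrected median of 0.42, 10000 random lists matched on expression, GC content and length had medians of up to 0.31, but such lists treat genes as independent, and the estimated correlation among Zfp genes was 0.317.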
